A study of Drosophila melanogaster with 9 samples.

How the data were processed

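RNA was measured in 9 libraries of larval fat body, 3 for each of the groups control_HS, InRCA_HS and InRCA_noHS, which were assigned from the sample titles. The submitters' processing notes name TopHat 1.3.2, Bowtie 0.12.7, Cufflinks 1.1.0 and the genome build dm3, with no role or order. The tool that counted reads, the annotation, the filters on genes and any use of strand are not given in the sources used here. Reads of overlapping genes, antisense genes and near-identical gene copies may therefore be shared.

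The deposited table held 1 value per gene and library, a non-negative signal that the values show to be counts adjusted to a common library size. It had 10372 genes and 9 value columns, and 0 columns of other samples were left out. The values have decimals, the lowest is 0.108 and 0 of 93348 are equal to 0. FPKM had been assumed before the data were examined, because the notes name Cufflinks. The decimals exclude raw counts, and the recovery of whole reads described next uses no gene lengths, which FPKM would need. The same test on log2 values was therefore kept, and the unit is called adjusted counts here. In 2 columns (control_HS replicate 1 and InRCA_noHS replicate 2) the low values were whole multiples of 1 step. In the other columns the steps changed with the level of the gene, as they do after a quantile adjustment of negative binomial counts. Undoing such an adjustment with 1 factor per library and a single dispersion of 0.0710, both estimated from the table, gave whole reads (to within 0.1) for 98.6% of the 38615 values up to 100. Values rebuilt from these reads differed from the deposited ones by a median of 0.00766%. Recovered reads summed to between 8748919 and 17598122 per library. The adjustment was made by the authors with a tool that the sources used here do not give, and it is part of every value given here.

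Genes were compared on log2(adjusted count + 1) with limma 3.58.1 in R 4.3.3. A single fit held all 9 libraries and 3 group means, with an empirical Bayes estimate of the spread that followed the mean level, and p-values were adjusted by the Benjamini-Hochberg method over all genes with a threshold of 0.05. A fold change on this scale understates the change of genes with low values. The planned filter, a mean of at least 1 over all libraries, removed 0 genes. The lowest recovered count was 1, so every gene in the table had reads in every library. Genes without reads in some library are thus not seen here, and could not be among the largest changes. The 3 comparisons were InRCA_HS against control_HS, InRCA_HS against InRCA_noHS and InRCA_noHS against control_HS. Genes that differed in 1 direction from both other groups in InRCA_HS were counted as well. Overlaps between comparisons that share libraries were set beside 100 simulations of unchanged groups, in which genes varied independently, and beside the overlap of independent lists. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

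The comparisons, tests, 30 gene lists and named genes were fixed before the data were examined, except where a test or list is said to have been chosen later. Of the lists, 29 had the minimum of 3 genes in the table and were tested with limma's camera, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of a comparison. None of the 38 list calls held with a correlation estimated from the data. InR, w and y came first among the named genes. Then followed, for each comparison and for the genes that differ from both other groups, the 10 highest and the 10 lowest log2 fold changes among genes past the threshold whose 3 libraries of 1 group all lay above or all below the 3 of the other. From each list discussed, up to 4 members with the smallest p were named, with Thor, Ilp6, upd2, bmm, Lip4, sug, Pepck and Hsp70 where a list needed them. Fewer genes were printed than the rule takes, in its order.

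Alternatives were a pseudocount of 0.1 or 5, no filter, a mean of at least 5, quantile normalization, TMM scaling, no intensity trend, array quality weights, a fit of only the 6 libraries compared, the replicate number as a block, a minimum of 1.5-fold, and each library left out in turn. A mean of at least 20 was added after the data had been seen. By the plan, the quasi-likelihood test of edgeR was to replace limma if the file held counts. The deposited values are adjusted and have decimals, so limma was kept. The quasi-likelihood test of edgeR 4.0.16 was run on the recovered reads. It called 118 genes higher and 162 lower in InRCA_HS against control_HS, 235 and 53 in InRCA_HS against InRCA_noHS, and 207 and 555 in InRCA_noHS against control_HS.

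The recovery and the tests were also tested on simulated data. In a simulated table, 100% of the whole counts behind low values were recovered exactly (5440 genes with such values). That table was made from the fitted means and factors through the same adjustment. It therefore tests the inversion, and not whether the authors used this adjustment. For InRCA_HS against control_HS, with 10371 genes tested and 50 genes changed by each fold, limma found 4% of the genes changed 1.5-fold, 22% of those changed 2-fold, 96% at 4-fold and 96% at 8-fold, with 8 false calls. The shares were 2%, 28%, 94% and 100% for InRCA_HS against InRCA_noHS, with 6 false calls. They were 6%, 20%, 96% and 96% for InRCA_noHS against control_HS, with 4 false calls. The simulated dispersion was 0.07. At this number of libraries changes under 2-fold are therefore mostly missed, and a gene that is not called is not shown to be unchanged.

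Gene symbols and identifiers are those of the deposited table. The annotation at hand belongs to a later build than dm3, so it was used only for transcript lengths, matched by identifier, and no coordinates are given. A control cross without heat shock was not analysed here, so the effects of heat, stock and receptor are not separated by any single comparison.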

Results

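Gene expression was measured by RNA-seq of total RNA, after removal of ribosomal RNA, in fat bodies of female Drosophila melanogaster larvae in the middle of the third instar. The fat body is the larval organ that stores fat and glycogen and secretes many blood proteins. Virgin females with the hs-GAL4 driver, which makes the GAL4 activator after a heat shock, were mated with males of stock 8263, which carry a GAL4-dependent transgene for a constitutively active insulin receptor (UAS-InR.A1325D), or with males of stock 6598, which do not. Larvae of the transgene cross were heated to 37 °C for 30 min (InRCA_HS) or moved to a fresh vial without heat and kept at 25 °C (InRCA_noHS), and larvae of the control cross were heated (control_HS). Fat bodies were collected after 6 h of recovery, by shearing and centrifugation. Each of the 3 groups had 3 libraries, and a control cross without heat shock was not analysed here. The labels do not say that the libraries of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

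The table held adjusted counts of 10372 genes. Whole reads recovered from it summed to 8748919 (InRCA_noHS replicate 1) to 17598122 (InRCA_HS replicate 3) per library. The 10 most abundant genes of a library took 32.3% to 40.0% of its adjusted counts. Across genes, which are not independent replicates, Pearson's correlation of log2 values was 0.962 to 0.980 within groups and 0.934 to 0.967 between groups. On the first principal component, which held 33.3% of the variance, control_HS replicate 1 lay at −14.8 and the other control_HS libraries at −55.6 and −37.7. This library also had the lowest of the 9 quality weights that limma estimated (0.420), so the counts of called genes in each comparison are also given without it.

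InR (FBgn0013984), the gene of the transgene, checked the labels. Its adjusted counts were 743, 785 and 826 in control_HS, 1821, 3662 and 2128 in InRCA_noHS, and 66688, 47774 and 60402 in InRCA_HS. The means were 785 ± 41.8, 2537 ± 986 and 58288 ± 9633 (SD, n = 3 in each group, as for every mean given from here on). InR was 73.5-fold higher in InRCA_HS than in control_HS (log2 fold change 6.20, SE 0.25, adjusted p = 6.87e-07) and 23.8-fold higher than in InRCA_noHS (adjusted p = 8.44e-06). It was also 3.09-fold higher in InRCA_noHS, without heat, than in control_HS (log2 fold change 1.63, adjusted p = 0.00467). Reads of the resident gene and of the transgene are counted together in these values. The eye colour gene w (FBgn0003996), a copy of which usually marks UAS transgenes, had means of 53.3 ± 15.2 in control_HS, 85.3 ± 23.2 in InRCA_noHS and 1341 ± 135 in InRCA_HS. It rose 25.3-fold in InRCA_HS against control_HS (adjusted p = 4.67e-06) and 15.9-fold against InRCA_noHS (adjusted p = 1.43e-05), and its log2 difference of 0.67 between InRCA_noHS and control_HS did not pass the test (adjusted p = 0.128). The body colour gene y was not analysed here.

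**Figure D1:**
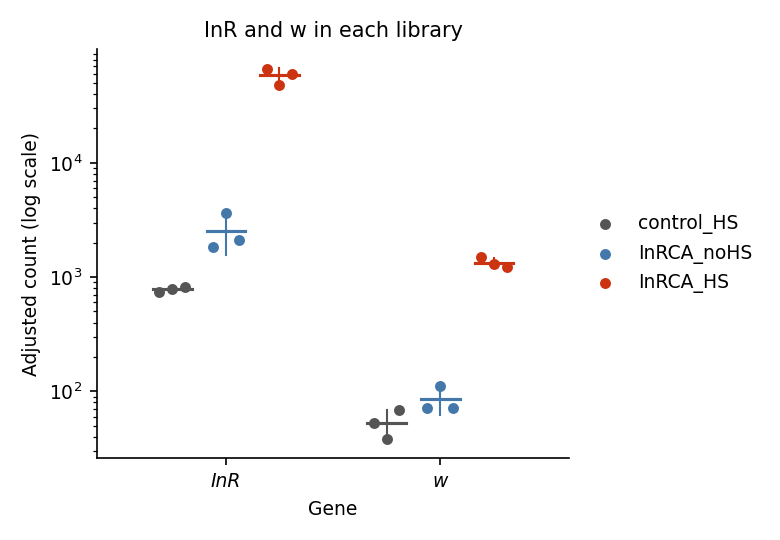
Adjusted counts (log scale) of InR and w in the 9 libraries; points are libraries, horizontal bars are group means and vertical lines are ± SD (n = 3 per group). All 3 InRCA_HS libraries lie above the other 6 for both genes, and InR in InRCA_noHS (mean 2537) lies above control_HS (mean 785).

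The comparison that the series names, InRCA_HS against control_HS, asks how a transient rise in insulin receptor activity changes expression in heat-shocked fat bodies. The male stock differs between these groups together with the receptor. In InRCA_HS, 115 of 10372 genes rose and 137 fell. After InR and w, the largest rises were those of CR40621 (log2 fold change 4.44), CG12224 (4.42), CG11893 (4.40), CG42847 (4.35), Sgs5 (4.18), CG32335 (3.98), Fbp2 (3.98) and CG9666 (3.96). Of these, CR40621, CG12224, CG42847, CG32335, Fbp2 and CG9666 were also among the largest rises in InRCA_noHS against control_HS, and Sgs5 rose there too. Their rises are thus not particular to larvae in which the receptor was induced by heat. Fbp2, which encodes a fat body protein, went from 8223 ± 2317 in control_HS to 127677 ± 25651 in InRCA_HS (SE 0.32, adjusted p = 0.000167). The salivary glue gene Sgs5 went from 988 ± 173 to 19420.0 ± 9308 (SE 0.40, adjusted p = 0.000706), and CG12224 from 83.4 ± 2.85 to 1849 ± 511 (SE 0.20, adjusted p = 1.68e-06). The largest falls were those of the cytochrome P450 gene Cyp6w1 (log2 fold change −3.34), the attacin gene AttB (−3.25), CG14273 (−3.06), CG15067 (−2.96), the immune-induced peptide gene IM1 (−2.85), CG4757 (−2.77), CG3264 (−2.77), CG10814 (−2.72), the diptericin gene Dpt (−2.60) and the stress gene TotC (−2.51). Cyp6w1 went from 189 ± 96.4 to 16.3 ± 6.39 (SE 0.44, adjusted p = 0.00493) and Dpt from 1653 ± 338 to 325 ± 236 (SE 0.44, adjusted p = 0.0172). Of the 62 calls of named genes in this comparison, 16 held in all 9 fits that left out 1 library: InR, w, CG12224, CG11893, CG42847, Sgs5, CG32335, Fbp2, Cyp6w1, CG14273, CG4757, Cyp6t1, Cyp309a1, CG15772, CG14567 and Obp99a. Every other gene said to rise or fall in this comparison lost its call without at least 1 library, with a highest adjusted p between 0.0592 (Cyp4p1, without InRCA_HS replicate 1) and 0.191 (ATPsyn-b, without InRCA_HS replicate 1).

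The counts of this comparison moved with single libraries. Without control_HS replicate 1, 325 genes rose and 636 fell. Without control_HS replicate 2 the counts were 34 and 27, and without control_HS replicate 3 they were 36 and 21. They were 71 and 74 without InRCA_noHS replicate 1, 70 and 79 without InRCA_noHS replicate 2, and 68 and 65 without InRCA_noHS replicate 3, whose group takes part through the shared estimate of the spread. Without InRCA_HS replicates 1, 2 and 3 they were 32 and 24, 44 and 39, and 183 and 165.

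The list of antimicrobial peptides and effectors of the Toll and Imd immune pathways passed the test downward in InRCA_HS against control_HS. Of 21 genes, 6 fell and 0 rose, and 14 were lower and 0 higher adjusted over the list alone. The median log2 fold change was −1.39 (limma camera, adjusted p = 1.96e-07, adjusted p = 0.551 with an estimated correlation). The list's median log2 level was 8.67 in InRCA_HS replicate 3, close to 8.73 in control_HS replicate 1, against 7.13 and 7.38 in the other InRCA_HS libraries and 9.79 and 9.76 in the other control_HS libraries. The 4 with the smallest p were Dpt, IM1, AttC (log2 fold change −1.76, adjusted p = 0.0308) and AttB (adjusted p = 0.0362), and reads of the attacin genes and of the IM cluster may be split between near-identical copies. Cytosolic ribosomal protein genes had a median of −0.64, with 82 of 86 below 0. Of these, 9 fell and 0 rose, and 61 were lower adjusted over the list alone (list adjusted p = 1.07e-24, adjusted p = 0.551 with an estimated correlation). Examples are RpS14a (11145 ± 1879 to 5551 ± 426, adjusted p = 0.0224) and RpL32 (20585 ± 2281 to 10095 ± 1431, adjusted p = 0.0234), followed by RpL17 (−1.03) and RpS21 (−0.82). RpL32, RpL17 and RpS21 lost their calls with quantile normalization, and related gene copies make such counts uncertain.

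Several metabolic lists passed the test downward in InRCA_HS against control_HS, with few single genes called. Lipolysis and beta-oxidation genes had a median of −0.64, although 0 of 21 passed the test over all genes. Adjusted over the list alone 1 was higher and 13 lower (list adjusted p = 8.65e-07, adjusted p = 0.557 with an estimated correlation). For glycolysis the median was −0.48 and all 13 genes were below 0, with Tpi (triose phosphate isomerase, −1.03, adjusted p = 0.0391) the 1 that fell. The list had 7 lower adjusted over the list alone (list adjusted p = 2.77e-05, adjusted p = 0.557 with an estimated correlation). Genes of gluconeogenesis, trehalose and glycogen had a median of −0.62 over 14, and fbp (fructose-1,6-bisphosphatase, −1.21, adjusted p = 0.0266) was the 1 that fell. Here 6 were lower adjusted over the list alone (list adjusted p = 9.91e-05, adjusted p = 0.557 with an estimated correlation). In the mitochondrial respiratory chain and ATP synthase, the median over 25 genes was −0.37 and ATPsyn-b fell (−0.72, adjusted p = 0.0499). In this list 1 was higher and 7 lower adjusted over the list alone (list adjusted p = 4.84e-05, adjusted p = 0.566 with an estimated correlation). The pentose phosphate pathway, 7 genes, had a median of −0.33, and Rpi fell (−0.80, adjusted p = 0.0488). There 3 were lower adjusted over the list alone (list adjusted p = 0.0282, adjusted p = 0.566 with an estimated correlation). Its list call ended with quantile normalization (adjusted p = 0.0668) and held in 7 of 9 fits without 1 library (highest adjusted p = 0.475, without control_HS replicate 2). Glutathione S-transferases and cytochromes P450 had a median of −0.41 over 88 genes, with 1 higher and 6 lower. The counts were 4 and 15 adjusted over the list alone (list adjusted p = 0.000126, adjusted p = 0.566 with an estimated correlation). In this list Cyp6t1 rose (2.35, adjusted p = 0.00287), and Cyp6w1, Cyp309a1 (−1.73) and Cyp4p1 (−1.91) fell. The lipogenesis list of 14 genes did not pass (median −0.27, adjusted p = 0.121), with 1 higher and 3 lower adjusted over the list alone. In it the ATP citrate lyase gene ATPCL rose (0.85, adjusted p = 0.0392) and the malic enzyme gene Men fell (−1.54, adjusted p = 0.0245). Without control_HS replicate 1 the lipogenesis list passed (adjusted p = 0.00562), and likewise without InRCA_HS replicate 3 (adjusted p = 0.0298).

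The ecdysone response list and some lists of markers of other tissues also passed in this comparison. Ecdysone response genes, which the moulting hormone controls, had a median of 0.42 over 18 genes, with 0 passing singly and 0 adjusted over the list alone (list adjusted p = 0.0119, adjusted p = 0.566 with an estimated correlation). Without control_HS replicate 2 this list's adjusted p was 0.267, and without InRCA_HS replicate 2 it was 0.0982. All 9 salivary gland markers were above 0, with a median of 1.37. Sgs5 rose, and 5 were higher adjusted over the list alone (list adjusted p = 9.17e-06, adjusted p = 0.551 with an estimated correlation). Reads of the Sgs genes may be shared between copies. Cuticle and epidermis markers had a median of 0.46 over 29, and 4 rose: Lcp4 (2.04), Lcp3 (2.16), Cpr11A (1.72) and Cpr78Ca (1.95). Adjusted over the list alone 6 were higher and 3 lower (list adjusted p = 0.0479, adjusted p = 0.566 with an estimated correlation). This list's call held in 3 of 9 fits without 1 library (highest adjusted p = 0.372, without InRCA_HS replicate 1) and ended with quantile normalization (adjusted p = 0.0643). Muscle markers had a median of −0.52 over 13, with 0 called and 2 lower adjusted over the list alone (list adjusted p = 0.00645, adjusted p = 0.566 with an estimated correlation). Without control_HS replicate 3 the muscle list's adjusted p was 0.0591.

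The other lists did not pass in InRCA_HS against control_HS. Of 19 insulin and TOR pathway components, InR was the only one called (list adjusted p = 0.852), with 1 higher and 1 lower adjusted over the list alone. The 16 FOXO target genes had a mean of 0.18 and a median of −0.17, with the test downward (adjusted p = 0.698). Among them InR rose and the activin-like ligand gene daw fell (−0.83, adjusted p = 0.0392), and 3 were higher and 5 lower adjusted over the list alone. InR, whose reads include those of the transgene, belongs to this list and to that of insulin and TOR components. Its rise, which the design sets, enters the means, tests and counts of both lists. Thor (0.78, adjusted p = 0.160), bmm (0.09, adjusted p = 0.834) and Pepck (−1.41, adjusted p = 0.0969) did not pass. In the list of 17 heat shock proteins and cofactors (adjusted p = 0.176), Hsp67Bc (2.64) and Hsp70Bb (2.64) rose and stv (−1.10) and Hsp68 (−1.38) fell. In that list 4 were higher and 6 lower adjusted over the list alone. The remaining adjusted p-values were 0.949 for ribosome biogenesis, 0.536 for aminoacyl-tRNA synthetases, 0.935 for autophagy and 0.790 for larval serum proteins and lipid carriers. They were 0.140 for fat body secreted signals, 0.865 for cell cycle and DNA replication, 0.973 for Turandot stress genes and 0.255 for sugar-responsive regulators and digestive enzymes. For markers of other tissues they were 0.523 (gut), 0.852 (hemocytes), 0.132 (neurons), 0.852 (Malpighian tubules) and 0.935 (male-biased and testis genes). The neuron list passed without InRCA_HS replicate 3 (adjusted p = 0.00363). The median and mean of the larval serum, cell cycle and Malpighian tubule lists differed in sign.

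InRCA_HS against InRCA_noHS compares the same cross with and without the heat shock that induces the receptor, and heat itself differs as well. In InRCA_HS, 182 genes rose and 83 fell, and the median over all genes was −0.14, so list medians for this comparison are given relative to it. The largest rises were those of the serine protease genes Ser7 (log2 fold change 6.20) and Sp212 (5.69), then CG32557 (5.37), CG6409 (5.35), the peptidoglycan recognition gene PGRP-SC2 (4.79), InR, the innexin gene inx7 (4.53), CG34194 (4.46), CG11898 (4.31) and CG31326 (4.24). Ser7 went from 5.27 ± 1.36 to 462 ± 126 (SE 0.36, adjusted p = 1.11e-05), Sp212 from 12.6 ± 12.0 to 503 ± 59.7 (SE 0.59, adjusted p = 0.000778) and CG6409 from 72.2 ± 28.6 to 2901 ± 946 (SE 0.32, adjusted p = 1.24e-05). The largest falls were those of CG5697 (−3.97), the predicted lipase gene CG5966 (−2.38), CG4269 (−2.36), CG14072 (−2.20), CR33218 (−2.18), CG34007 (−2.12), Cyp6a2 (−2.10), Cyp6a21 (−1.92), CG17739 (−1.92) and CG7173 (−1.83). CG5966 went from 11205 ± 248 to 2149 ± 126 (SE 0.22, adjusted p = 0.000365). With TMM scaling 238 genes rose and 59 fell, which is 80.1% higher instead of 68.7%. The recovered reads gave 235 and 53 (81.6%) with edgeR.

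Of the 54 calls of named genes against InRCA_noHS, 30 held in all 9 fits without 1 library, among them those of InR, Ser7, Sp212, CG32557, CG6409, PGRP-SC2, inx7, CG34194, CG31326, CG5966, CG4269, CG34007, Cyp6a21, ATPCL, ACC, Pgd, IM3, Mtk, Ilp6, Hsp83, CG33138, Aats-cys, Cpr11A, GstD4 and Cyp6d5. The other calls ended without at least 1 library, with a highest adjusted p between 0.0533 (CG11898, without InRCA_noHS replicate 2) and 0.159 (CG7173, without InRCA_noHS replicate 3). Zw reached 0.0558 and IM1 0.130 without InRCA_noHS replicate 3, and AcCoAS and CG3523 0.119 without InRCA_noHS replicate 2. Without control_HS replicate 1, 220 genes rose and 116 fell. Without InRCA_noHS replicates 1, 2 and 3 the counts were 106 and 35, 85 and 21, and 90 and 16. Without InRCA_HS replicates 1, 2 and 3 they were 109 and 24, 120 and 45, and 108 and 37.

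The lipogenesis list passed the test upward in InRCA_HS against InRCA_noHS. Of 14, 5 rose and 0 fell, and 6 were higher and 1 lower adjusted over the list alone. The list's median lay 0.74 above that of all genes (camera, adjusted p = 5.98e-06, adjusted p = 0.754 with an estimated correlation). ATPCL went from 2536 ± 319 to 6878 ± 209.7 (log2 fold change 1.45, SE 0.18, adjusted p = 0.00278) and the acetyl-CoA carboxylase gene ACC from 883 ± 115 to 5421 ± 1733 (2.58, SE 0.35, adjusted p = 0.00412). The acetyl-CoA synthetase gene AcCoAS (1.54, adjusted p = 0.0270) and the fatty acid synthase gene CG3523 (1.76, adjusted p = 0.0273) rose too, from 1926 ± 556 to 5501 ± 887 and from 8728 ± 3285 to 29297 ± 9193. In the pentose phosphate pathway, which supplies NADPH, 2 of 7 rose and 4 were higher adjusted over the list alone (relative median 0.80, list adjusted p = 0.00662, adjusted p = 0.754 with an estimated correlation). These were the dehydrogenase genes Pgd (1011 ± 30.7 to 3163 ± 435, 1.64, adjusted p = 0.00811) and Zw (163 ± 34.0 to 645 ± 81.0, 1.99, adjusted p = 0.0104). Against control_HS, ATPCL was the only one of these 6 genes to pass the test. For ACC, AcCoAS, CG3523, Pgd and Zw the log2 fold changes of InRCA_HS against control_HS were −0.52, −0.24, −0.29, −0.01 and 0.26, with adjusted p from 0.482 (ACC) to 0.988 (Pgd).

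**Figure D2:**
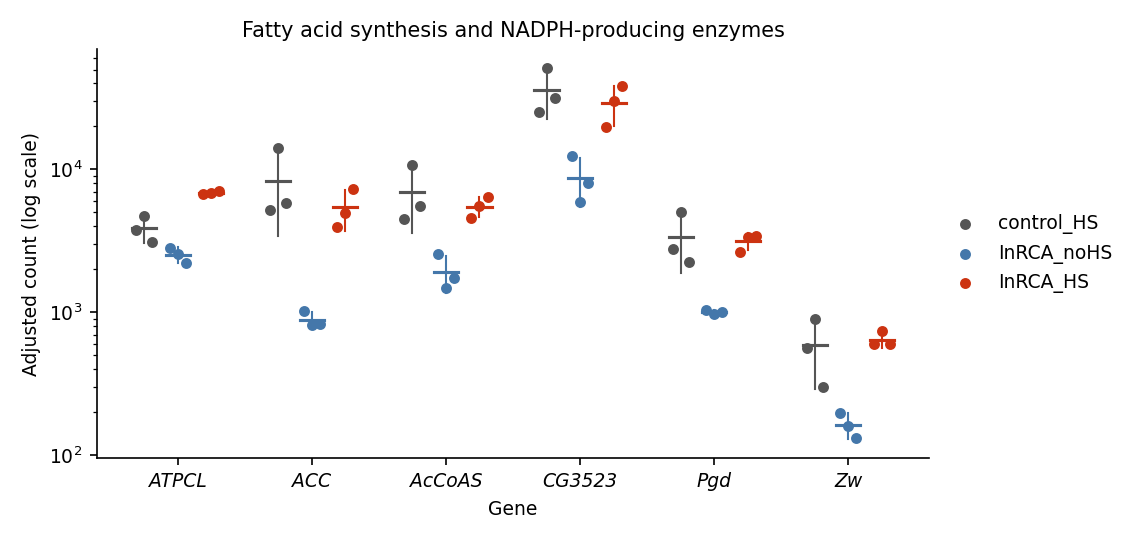
Adjusted counts (log scale) of genes of fatty acid synthesis and NADPH production in the 9 libraries; points are libraries, horizontal bars are group means and vertical lines are ± SD (n = 3 per group). ACC averages 883 in InRCA_noHS against 5421 in InRCA_HS and 8353 in control_HS, while ATPCL is highest in InRCA_HS (mean 6878).

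The antimicrobial list passed the test upward in InRCA_HS against InRCA_noHS: 4 of 21 rose and 0 fell, and 5 were higher and 1 lower adjusted over the list alone. The relative median was 0.99 (list adjusted p = 1.43e-06, adjusted p = 0.572 with an estimated correlation). They were IM3 (101 ± 62.6 to 1318 ± 863, log2 fold change 3.77, adjusted p = 0.00615), the metchnikowin gene Mtk (93.8 ± 39.0 to 1001 ± 609.6, 3.20, adjusted p = 0.0101), IM2 (2.71, adjusted p = 0.0188) and IM1 (2.49, adjusted p = 0.0329). InRCA_HS replicate 3 stood apart, with a median log2 level of the list of 8.67 against 7.13 and 7.38 in the other InRCA_HS libraries and 6.36 to 6.99 in InRCA_noHS. IM1 and IM2 lost their calls without InRCA_HS replicate 2 or 3 and without InRCA_noHS replicate 1 or 3, and IM1 also without control_HS replicate 3 (highest adjusted p = 0.130 and 0.0976). Hemocyte markers lay 0.78 above all genes in the median over 7, with 0 called and 0 adjusted over the list alone (list adjusted p = 0.0355, adjusted p = 0.754 with an estimated correlation). This call held in 5 of 9 fits without 1 library (highest adjusted p = 0.284, without InRCA_HS replicate 3). Among aminoacyl-tRNA synthetases, Aats-cys rose (1.40, adjusted p = 0.00646), 3 of 21 were higher adjusted over the list alone, and the relative median was 0.37 (list adjusted p = 9.04e-06, adjusted p = 0.572 with an estimated correlation). Ribosomal protein genes, all 86 below 0, had a relative median of −0.20 with 0 called and 0 adjusted over the list alone (list adjusted p = 1.43e-06, adjusted p = 0.754 with an estimated correlation). Ribosome biogenesis genes had a relative median of −0.14 over 25 with 0 called and 0 adjusted over the list alone (list adjusted p = 0.0271, adjusted p = 0.878 with an estimated correlation). The call ended without InRCA_noHS replicate 2 (adjusted p = 0.227) and without InRCA_HS replicate 1 (adjusted p = 0.396).

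Ecdysone response genes had a relative median of −0.43 with 0 of 18 called and 0 adjusted over the list alone (list adjusted p = 0.0461, adjusted p = 0.754 with an estimated correlation). The list's call held in 4 of 9 fits without 1 library (highest adjusted p = 0.288, without InRCA_HS replicate 3) and ended with a minimum mean of 5 (adjusted p = 0.0502). Cuticle markers had a relative median of 0.61, and Cpr11A rose (3.68), 1 of 29 and 1 adjusted over the list alone (list adjusted p = 4.32e-05, adjusted p = 0.572 with an estimated correlation). Salivary gland markers (relative median 0.81, list adjusted p = 0.00841, adjusted p = 0.754 with an estimated correlation) and muscle markers (0.37, list adjusted p = 0.00698, adjusted p = 0.754 with an estimated correlation) had 0 genes called and 1 higher each adjusted over the list alone. Without InRCA_noHS replicate 2 the salivary list's adjusted p was 0.285 and the muscle list's 0.244, and without InRCA_HS replicate 2 the salivary list's was 0.0826.

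The insulin-like peptide gene Ilp6 fell in InRCA_HS against InRCA_noHS, from 2144 ± 349 to 598 ± 39.8 (log2 fold change −1.83, SE 0.18, adjusted p = 0.000575), as did daw, from 1849 ± 179 to 885 ± 156 (−1.07, adjusted p = 0.0108). They belong to the fat body secreted signals, a list of 10 that did not pass (adjusted p = 0.278), with 1 higher and 2 lower adjusted over the list alone. In it upd2 did not pass either (1.82, adjusted p = 0.0655). In the list of lipolysis and beta-oxidation (adjusted p = 0.118), the carnitine palmitoyltransferase gene whd (−1.04, adjusted p = 0.0188) and the acyl-CoA dehydrogenase gene CG12262 (−1.21, adjusted p = 0.0305) fell, and 1 was higher and 4 lower adjusted over the list alone. This list passed with quantile normalization (adjusted p = 0.0446), without InRCA_noHS replicate 2 (adjusted p = 0.00642) and without InRCA_HS replicate 2 (adjusted p = 0.0255). Among heat shock proteins (list adjusted p = 0.617), Hsp83 of the Hsp90 family fell from 18532 ± 1748 to 7814 ± 1030.5 (−1.25, adjusted p = 0.00582) and Hsp70Bb, which has near-identical copies, rose from 70.1 ± 56.0 to 528 ± 130.1 (3.14, adjusted p = 0.0155). CG33138, the glycogen branching enzyme, rose (2.13, adjusted p = 0.00814) in a list that did not pass (gluconeogenesis, trehalose and glycogen, adjusted p = 0.987). The other lists that did not pass had adjusted p between 0.209 (neuron markers) and 0.987 (glycolysis, sugar-responsive regulators, and male-biased and testis genes). The neuron list passed without InRCA_HS replicate 3 (adjusted p = 0.00271) and the gut list without InRCA_noHS replicate 1 (adjusted p = 0.00244). Medians and means, or the test, differed in sign for the lists of insulin and TOR components, FOXO targets, gluconeogenesis, larval serum proteins, Turandot genes, sugar-responsive regulators, Malpighian tubule markers and male-biased genes. The lists of insulin and TOR components and of FOXO targets include InR, the gene of the transgene.

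InRCA_HS is the only group with both the transgene and the heat shock, so genes that differ from both other groups in 1 direction are set apart neither by the stock alone nor by heat alone. Stock and heat acting together could also give such a difference, because a control cross without heat shock was not analysed here. Such genes are therefore not shown, by this alone, to respond to the receptor. There were 19 genes higher and 12 lower in InRCA_HS than in both other groups. The first 10 of the higher ones, ordered by the mean of the log2 fold changes against control_HS and InRCA_noHS, were InR, w, Ser7 (1.87 and 6.20), Hsp70Bb (2.64 and 3.14), Cpr11A (1.72 and 3.68), CG4991 (2.45 and 2.67), CG15772 (2.40 and 2.34), bnb (1.28 and 2.74), CG14567 (1.66 and 2.08) and CG11236 (1.06 and 2.23). CG15772 averaged 359 ± 109 in control_HS, 375 ± 107 in InRCA_noHS and 1918 ± 688 in InRCA_HS (adjusted p = 0.00409 and 0.00305). ATPCL, from the lipogenesis list, was also among the 19 (0.85 and 1.45). The first 10 of the lower ones were CG14072 (−1.66 and −2.20), CG4269 (−1.32 and −2.36), CG5966 (−0.96 and −2.38), CG8129 (−1.78 and −1.43), the phosphoserine phosphatase gene aay (−1.23 and −1.32), the adipokinetic hormone receptor gene GRHR (−1.17 and −1.18), the odorant-binding protein gene Obp99a (−1.31 and −0.92), Cyp6d5 (adjusted p = 0.0234 and 0.00730), daw (−0.83 and −1.07) and CG8026 (−0.93 and −0.92). GRHR averaged 504 ± 124, 501 ± 94.5 and 219 ± 29.6 in control_HS, InRCA_noHS and InRCA_HS (adjusted p = 0.0242 and 0.0180).

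**Figure D3:**
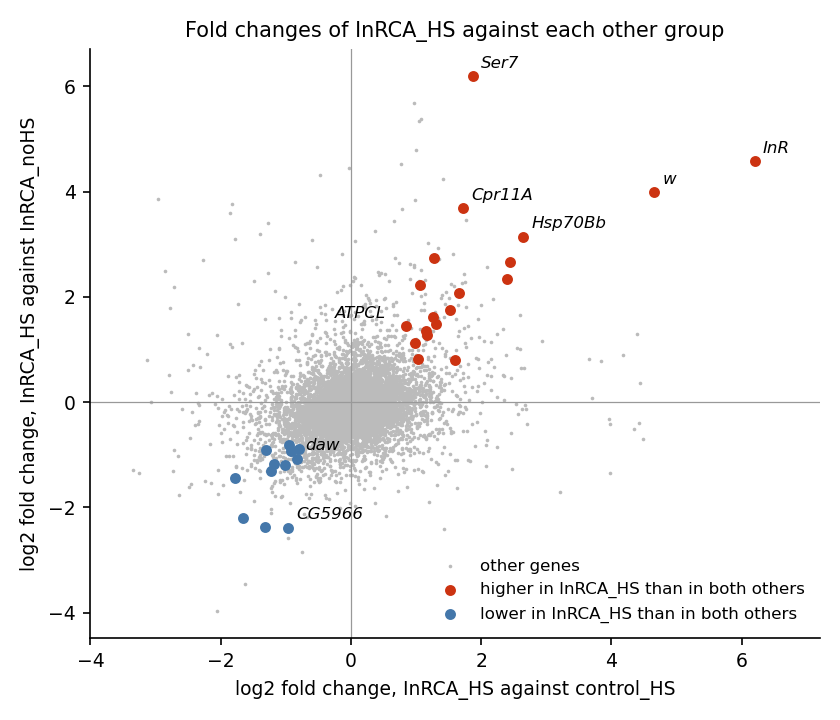
Log2 fold changes of all 10372 genes in InRCA_HS against control_HS (horizontal axis) and against InRCA_noHS (vertical axis); each point is a gene. The 19 genes higher in InRCA_HS than in both other groups are red and the 12 lower ones blue, with InR at 6.20 and 4.58.

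Both comparisons use the InRCA_HS libraries, so their overlap is above 0 by chance. Independent lists of these sizes would share 2.02 higher and 1.1 lower genes, and unchanged groups simulated 100 times shared 0.03 genes on average. The covariance of the fold changes was 0.0820 against 0.0585 in the simulations, a difference of 0.0235. Across genes their correlation was 0.263 against 0.499 in the simulations, and 59.0% of genes had the same sign against 66.6%. With 3 shared libraries no split leaves 2 in each part, so part of the excess may come from the shared libraries. Without control_HS replicates 1, 2 and 3, the genes higher and lower than both groups numbered 26 and 42, 13 and 5, and 4 and 1. They numbered 10 and 1, 11 and 1, and 10 and 2 without InRCA_noHS replicates 1, 2 and 3, and 4 and 0, 6 and 5, and 18 and 10 without InRCA_HS replicates 1, 2 and 3. Of the genes named here, InR, w, CG15772 and CG14567 held both calls in all 9 fits.

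InRCA_noHS against control_HS sets the groups without an induced receptor side by side. Stock and heat shock both differ, and the comparison also tests the difference between the other comparisons. It gave 337 genes higher and 392 lower in InRCA_noHS, with a median over all genes of 0.12, relative to which list medians are given. The largest rises were those of CG32335 (log2 fold change 5.32), the peptidoglycan recognition gene PGRP-SB2 (5.17), CG11192 (4.91), CG42847 (4.86), CG12224 (4.81), Fbp2 (4.38), CG9666 (4.28), CR40621 (4.08), the receptor gene Lgr1 (3.74) and CG43291 (3.62). Fbp2 went from 8223 ± 2317 in control_HS to 171113 ± 42083 in InRCA_noHS (SE 0.32, adjusted p = 6.19e-05). The largest falls were those of CG15067 (−6.82), IM3 (−5.59), IM4 (−5.44), IM1 (−5.34), IM2 (−4.98), CG10814 (−4.91), the potassium channel gene Ork1 (−4.87), CG11898 (−4.78), Sp212 (−4.72) and Ugt36Bc (−4.68). CG15067 went from 778 ± 229 to 7.17 ± 6.32 (SE 0.58, adjusted p = 0.000191). With TMM scaling 220 genes rose and 541 fell, which is 28.9% higher instead of 46.2%. The recovered reads gave 207 and 555 (27.2%) with edgeR, and quantile normalization gave 271 and 494 (35.4%).

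Of the 65 calls of named genes in InRCA_noHS against control_HS, 36 held in all 9 fits without 1 library, including those of the 20 genes just listed except PGRP-SB2 and CR40621, and those of InR, ACC, CG3523, AcCoAS, Pgd, Tal, Mtk, Pgi, CG33138, Ilp6, Sgs5, TotC, LysB, Mal-A6, Cyp4ad1, Cyp6a21, Cyp6t1 and Cyp309a1. The others ended without at least 1 library, with a highest adjusted p between 0.0501 (Eip63E, without control_HS replicate 2) and 0.148 (Best2, without control_HS replicate 2). Without control_HS replicate 1, 681 genes rose and 740 fell. Without control_HS replicates 2 and 3 the counts were 103 and 164, and 219 and 224. Without InRCA_noHS replicates 1, 2 and 3 they were 168 and 253, 107 and 168, and 96 and 179.

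Antimicrobial genes were the list with the smallest p in InRCA_noHS against control_HS. Of 21, 11 fell and 1 rose, and 16 were lower and 1 higher adjusted over the list alone. The relative median was −2.11 (camera, adjusted p = 7.75e-15, adjusted p = 0.247 with an estimated correlation). IM1 went from 2177 ± 566 to 62.4 ± 46.7 (adjusted p = 0.000393), IM3 from 4300.3 ± 1641 to 101 ± 62.6 (adjusted p = 0.000393), IM2 from 2000.1 ± 572 to 69.9 ± 48.8 (adjusted p = 0.000461) and Mtk from 2177 ± 454 to 93.8 ± 39.0 (log2 fold change −4.59, adjusted p = 0.000981). The gene that rose, named after its value was seen, was pirk, an inhibitor of the Imd pathway (1.28). Hemocyte markers, with 0 of 7 called (0 adjusted over the list alone), had a relative median of −0.75 (list adjusted p = 0.0440, adjusted p = 0.598 with an estimated correlation). Their list call held in 4 of 9 fits without 1 library (highest adjusted p = 0.132, without control_HS replicate 2) and ended with TMM scaling (adjusted p = 0.0577) and quantile normalization (adjusted p = 0.0612).

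**Figure D4:**
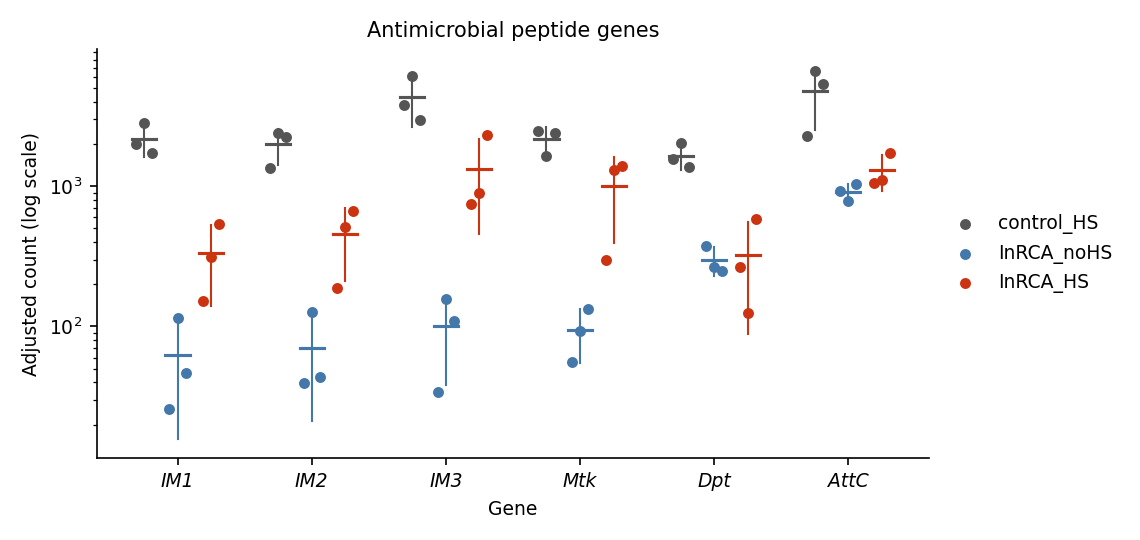
Adjusted counts (log scale) of antimicrobial peptide genes in the 9 libraries; points are libraries, horizontal bars are group means and vertical lines are ± SD (n = 3 per group). For IM1, IM2, IM3 and Mtk the InRCA_noHS libraries lie below all others (means 62.4, 69.9, 101 and 93.8).

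Several metabolic lists passed the test downward in InRCA_noHS against control_HS, with few single genes called in most. Of 14 lipogenesis genes 6 fell and 0 rose, and 10 were lower adjusted over the list alone (relative median −0.85, list adjusted p = 3.49e-08, adjusted p = 0.450 with an estimated correlation). The 4 with the smallest p were ACC (8353 ± 4948 to 883 ± 115, log2 fold change −3.09, adjusted p = 0.000958), CG3523 (−2.05, adjusted p = 0.00850), AcCoAS (−1.78, adjusted p = 0.00850) and HLH106, the SREBP gene (−0.93, adjusted p = 0.0277). In the pentose phosphate pathway 4 of 7 fell: Pgd (−1.65), Tal (−1.65), Zw (−1.72) and CG8036 (−0.94). In it 6 were lower adjusted over the list alone (relative median −1.06, list adjusted p = 3.61e-06, adjusted p = 0.450 with an estimated correlation). Pgi (−1.62) and Eno (−0.99) fell among 13 glycolysis genes, as also adjusted over the list alone (2; relative median −0.54, list adjusted p = 0.000192, adjusted p = 0.598 with an estimated correlation). CG33138 (−2.28) and the trehalose synthesis gene Tps1 (−1.35) fell among 14 genes of gluconeogenesis, trehalose and glycogen, where 1 was higher and 4 lower adjusted over the list alone (relative median −0.61, list adjusted p = 0.000212, adjusted p = 0.562 with an estimated correlation). Acsl (adjusted p = 0.0326) and Acox57D-d (adjusted p = 0.0345) fell among 21 lipolysis and beta-oxidation genes, with 2 lower adjusted over the list alone (relative median −0.34, list adjusted p = 0.00397, adjusted p = 0.631 with an estimated correlation). This list's call ended without InRCA_noHS replicate 2 (adjusted p = 0.115), without control_HS replicate 3 (adjusted p = 0.0795) and with quantile normalization (adjusted p = 0.0572). Aats-asp (−0.78) and Aats-asn (−0.70) fell among 21 aminoacyl-tRNA synthetases, with 4 lower adjusted over the list alone (relative median −0.42, list adjusted p = 5.68e-06, adjusted p = 0.450 with an estimated correlation). Glutathione S-transferases and cytochromes P450 had 4 of 88 higher and 10 lower, and 6 and 15 adjusted over the list alone (relative median −0.33, list adjusted p = 0.00112, adjusted p = 0.631 with an estimated correlation). In 3 lists 0 genes were called, and 0 adjusted over the list alone. The 86 ribosomal proteins had a relative median of −0.46 (list adjusted p = 4.22e-09, adjusted p = 0.598 with an estimated correlation). For the respiratory chain it was −0.31 (list adjusted p = 0.00183, adjusted p = 0.598 with an estimated correlation), and without control_HS replicate 2 this list's adjusted p was 0.0929. Ribosome biogenesis had a relative median of 0.19 (list adjusted p = 0.0440, adjusted p = 0.730 with an estimated correlation). This last call held in 4 of 9 fits without 1 library (highest adjusted p = 0.194, without InRCA_noHS replicate 2) and ended with TMM scaling (adjusted p = 0.0758).

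The ecdysone response list passed the test upward in InRCA_noHS against control_HS: 6 of 18 rose and 0 fell, and 9 were higher adjusted over the list alone (relative median 0.71, list adjusted p = 0.000192, adjusted p = 0.450 with an estimated correlation). Examples are Eip63E (432 ± 123 to 909 ± 86.1, adjusted p = 0.0112), Hr39 (1.45, adjusted p = 0.0241), Eip71CD (1.29) and Eip93F (0.82). Salivary gland markers moved with them (relative median 1.21, list adjusted p = 0.0352, adjusted p = 0.598 with an estimated correlation): Sgs5 rose (3.29, adjusted p = 0.00134), and 6 of 9 were higher and 1 lower adjusted over the list alone. This list call held in 5 of 9 fits without 1 library (highest adjusted p = 0.181, without InRCA_noHS replicate 1). The muscle marker list passed downward (median −0.88 over 13, before the median over all genes is taken off; list adjusted p = 1.35e-06, adjusted p = 0.450 with an estimated correlation), with Act87E (−0.96) and Mlc2 (13363 ± 3345 to 5833 ± 2242, −1.23, adjusted p = 0.0313) called and 8 lower adjusted over the list alone. The list's median log2 level in control_HS replicate 1, 10.8, lay among the InRCA_noHS libraries (10.6 to 11.1), below control_HS replicates 2 and 3 (11.6 and 11.7).

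In lists that did not pass in InRCA_noHS against control_HS, Ilp6 rose (1.18, adjusted p = 0.00432; fat body secreted signals, list adjusted p = 0.924), as did Hsp67Bc (2.76) and Hsp23 (1.42) among heat shock proteins (list adjusted p = 0.580). In that list stv (−1.16) and Hsp68 (−1.37) fell. Fbp2 and NLaz (2.37) rose and the ferritin genes Fer1HCH (−1.08) and Fer2LCH (−1.06) fell among larval serum proteins and lipid carriers (list adjusted p = 0.154; mean and median differ in sign). TotC fell (−3.13; Turandot genes, list adjusted p = 0.782), as did sug (−1.77, adjusted p = 0.0369; sugar-responsive regulators, list adjusted p = 0.278). The gut markers Mal-A6 (adjusted p = 0.00542) and LysB (adjusted p = 0.00891) and the Malpighian tubule marker Best2 (1.16) rose, and Cpr11A (−1.96), Cpr67Fb (−1.58) and Cpr47Eb (−3.32) fell among cuticle markers, in lists with adjusted p of 0.238, 0.924 and 0.283. The gut list passed without InRCA_noHS replicate 1 (adjusted p = 0.000830). The others had adjusted p of 0.408 (insulin and TOR components), 0.903 (FOXO targets), 0.421 (autophagy), 0.453 (cell cycle), 0.788 (neuron markers) and 0.924 (male-biased genes).

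The calls of the comparisons overlapped. Of the genes higher in InRCA_HS than in control_HS, 71 of 115 (61.7%) were also higher in InRCA_noHS than in control_HS, and 67 of the 137 lower ones (48.9%) were also lower. Independent lists would share 3.74 and 5.18 genes, simulated unchanged groups shared 0.02, and the covariance of fold changes was 0.249 against 0.0588 in the simulations, a difference of 0.190. The correlation across genes was 0.637 against 0.502, and 70.9% of genes had the same sign against 66.7%. Of the genes higher in InRCA_HS than in InRCA_noHS, 138 of 182 (75.8%) were lower in InRCA_noHS than in control_HS, where independent lists would share 6.88. In these pairs too the shared group has only 3 libraries, so part of the excess may come from the shared libraries.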

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

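A minimum mean of 20 was chosen after the data had been seen. The edgeR test was planned for the case that whole reads could be recovered, but the way of recovering them was worked out on the data. The plan also had edgeR replace limma if the file held counts. The deposited values are adjusted counts with decimals, and limma was kept as the main test. Of the recomputed counts of called genes, 96 stayed within 1.5 times the reported ones, 14 were larger and 66 smaller. Of the list results 1461 kept their side of the threshold, 9 newly passed and 96 no longer did, 38 of these with an estimated correlation. For named genes the numbers were 8392, 224 and 687. No direction of a call reversed. The pseudocounts, the minimum means of 5 and 20, quantile normalization and the 1.5-fold minimum left every count within 1.5 times the reported one. Leaving out the filter moved nothing, since it removed 0 genes.

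Without an intensity trend the genes higher and lower numbered 46 and 44 in InRCA_HS against control_HS, 111 and 34 against InRCA_noHS, 200 and 246 in InRCA_noHS against control_HS, and 7 and 1 against both groups. Array quality weights gave 331 and 569, 244 and 146, 742 and 704, and 39 and 42 in the same order. A fit of only the 6 libraries compared gave 30 and 26, 233 and 142, 310 and 346, and 5 and 1. TMM scaling lowered the genes higher in InRCA_noHS than in control_HS to 220, and edgeR on the recovered reads to 207. With edgeR 53 genes were lower in InRCA_HS than in InRCA_noHS. TMM scaling and edgeR also shifted the median over all genes. In InRCA_noHS against control_HS it went from 0.12 to 0.000674 and 0.000224, and in InRCA_HS against InRCA_noHS from −0.14 to −0.0234 and −0.0164. The cause was not tested for any of the changes in this paragraph.

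Over the fits that left out 1 library, InRCA_HS against control_HS had 32 (without InRCA_HS replicate 1) to 325 genes higher and 21 (without control_HS replicate 3) to 636 lower. Against InRCA_noHS it had 85 (without InRCA_noHS replicate 2) to 220 higher and 16 (without InRCA_noHS replicate 3) to 116 lower. InRCA_noHS against control_HS had 96 (without InRCA_noHS replicate 3) to 681 higher and 164 (without control_HS replicate 2) to 740 lower. Against both groups there were 4 (without control_HS replicate 3 or InRCA_HS replicate 1) to 26 higher and 0 (limma, without InRCA_HS replicate 1) to 42 lower. In that fit 1315 and 1259 genes had an unadjusted p under 0.05 against control_HS and InRCA_noHS, and edgeR with all libraries gave 9. All 8 highest counts came without control_HS replicate 1, and the cause was not tested. Each of these fits has fewer libraries to estimate the spread from. At an unadjusted p under 0.05, 1899, 1540 and 2453 genes differed in the 3 comparisons with all libraries.

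The replicate numbers were checked for pairing. Deviations of libraries with the same number correlated between −0.245 and 0.121, others between −0.245 and 0.293, and 3 of 9 libraries correlated best with their own number. No pairing by number was therefore seen. With 3 libraries per group this cannot show that pairing, or batches that cut across the numbers, were absent. With the replicate number as a block the counts were 91 and 95, 130 and 56, 251 and 300, and 10 and 5 against both groups. At these depths and 3 libraries per group, simulated changes of 2-fold were found in 20% to 28% of genes and changes of 4-fold in 94% to 96%.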

Other observations

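Tests chosen only after their result had been seen were the covariance and graded receptor tests, the hemocyte tests, the test of the authors' adjustment and all counts over other splits of the libraries, and the secretory list itself was drawn up after the data had been seen. Median log2 fold changes of gene lists in this section are given before the median over all genes is taken off.

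Most of the listed genes of the secretory pathway, which fold proteins in the endoplasmic reticulum and carry them to the surface, were lowest in InRCA_noHS. In all, 138 genes were lower in InRCA_noHS than in both heat-shocked groups and 25 were higher. Without 1 library the 25 became 6 (InRCA_noHS replicate 3), 8 (InRCA_noHS replicate 2), 13 (InRCA_HS replicate 1 or 3) or 35 (control_HS replicate 1), and 19 to 31 otherwise. Of 59 secretory genes 19 were among the 138. The list was made because such genes had been seen there, so no p-value is given for it. Between InRCA_noHS and control_HS 36 of the 59 fell and 0 rose, and all 59 log2 fold changes were below 0 (median −0.86). Between InRCA_HS and InRCA_noHS 19 rose and 0 fell (median 0.69), and 2 of 59 were below 0 (Ero1L −0.31 and opm −0.03). Between InRCA_HS and control_HS 1 fell and 0 rose, with 37 of 59 below 0 (median −0.11). Hemocyte markers had medians of −0.63 in InRCA_noHS against control_HS and 0.64 in InRCA_HS against InRCA_noHS, and muscle markers −0.88 and 0.23. The chaperone genes Gp93 (−2.52 against control_HS, and 1.60 in InRCA_HS against InRCA_noHS) and Hsc70-3 (−1.70 and 1.32) were among them, as were CaBP1 (−2.89 and 1.58), Manf (−2.11 and 1.57) and the translocon gene Sec61beta (−0.93 and 1.38). These genes were chosen after their values were seen.

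Whether the whole class fell stays open: the 23 secretory members that were not called had a median of −0.42, but the list was made from the pattern and cannot test it. Gene length and expression level are argued against as the source, since random lists of other genes matched on both had a median of −0.01, against −0.86 for the 57 members with a length. A factor of the authors' library size adjustment that put InRCA_noHS too low is argued against by the median over all genes, which lay at 0.12 against control_HS (0.0987 to 0.134 without 1 library) and at −0.14 in InRCA_HS against InRCA_noHS (−0.143 to −0.120), so these falls are relative to other genes. Without 1 library the 138 became 51 (InRCA_noHS replicate 2), 56 (InRCA_noHS replicate 3), 77 (InRCA_noHS replicate 1 or InRCA_HS replicate 3), 88 (InRCA_HS replicate 1), 93 (InRCA_HS replicate 2), 98 (control_HS replicate 3), 101 (control_HS replicate 2) or 166 (control_HS replicate 1). Heat shock, which the design names, stays open, untested, together with handling and a different mix of cell types. Of 7 hemocyte markers 0 were called, which does not show them unchanged. Their list passed downward in InRCA_noHS against control_HS (camera, adjusted p = 0.0440, adjusted p = 0.598 with an estimated correlation). The markers' median log2 level in control_HS replicate 3 (7.27) lay below the InRCA_noHS libraries (7.34 to 7.88), and in control_HS replicates 1 and 2 it was 8.63 and 8.76.

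Of the 252 genes called between InRCA_HS and control_HS, 138 were also called in the same direction between InRCA_noHS and control_HS, where independent lists would share 8.91. The covariance of the fold changes was 0.249 against 0.0582 (SD 0.00205) in a separate simulation, a difference of 0.191. The simulation varied genes independently, while genes of a library can vary together, so its SD can be too small. Chance values of the shared control libraries therefore stay open. A single control library was not the source of all shared calls. Without 1, the lowest number was 35 of 61 (without control_HS replicate 2), with 590 of 961 without replicate 1 and 47 of 57 without replicate 3. Independent lists would share 0.765 in the lowest case, but these fits still share the remaining control libraries. That value is therefore too low a benchmark, and how much of the overlap came from 1 library stays open. Graded action of the receptor, which was already 3.09-fold higher in InRCA_noHS, cannot be told apart from its absence: the shared genes' signed median from InRCA_noHS to InRCA_HS was −0.0202 (−0.10 to 0.06 without 1 library), and 64 of 138 moved further. The male stock, and any difference in developmental timing that goes with it, could give the same overlap and stay open, untested. So does a different mix of tissues. Of the lists of markers of other tissues, salivary gland and muscle passed in both InRCA_HS and InRCA_noHS against control_HS, with medians of 1.37 and 1.33, and −0.52 and −0.88.

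In 8 of 21 antimicrobial genes all 3 InRCA_noHS libraries lay below the other 6, and pirk was called higher there than in control_HS. Interchangeable libraries would place 1.19% of genes lowest in InRCA_noHS in this way. The share over all genes is not given here, and the pattern was seen in these same data. The 8 genes are therefore a description and not a test. A single library is argued against as the source: the median log2 fold change against control_HS was −1.99, and at its weakest −1.69 (without control_HS replicate 2). Hemocytes, blood cells that could have come with the preparation, are argued against as the whole source of the difference from control_HS. Their markers had a median of −0.63 (−0.81 to −0.36 without 1 library) against −1.69 for the antimicrobial genes at their weakest. The median rests on 7 of 11 planned markers. These spread from Sr-CI (163 ± 84.0 in control_HS to 60.9 ± 7.26 in InRCA_noHS) to crq (908 ± 90.6 to 1045 ± 113). What part hemocytes had is therefore not measured. For the difference between InRCA_HS and InRCA_noHS hemocytes stay open: their markers had a median of 0.64 (0.37 to 0.79) and the antimicrobial genes 0.85 (0.69 to 1.09), and the most abundant marker, Hml, averaged 2054 ± 742, 1112 ± 217 and 1973 ± 764 in control_HS, InRCA_noHS and InRCA_HS, and Pxn 1932 ± 394, 1210 ± 142 and 1742 ± 549. Heat shock and handling remain open, untested. The male stock stays open, untested, only for the difference from control_HS, since both InRCA groups come from the same cross.

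The libraries were also split in other ways. The 252 genes called between InRCA_HS and control_HS compare with at most 0 in the other splits of these 6 libraries (limma, 1 of 10 splits as large), the 265 against InRCA_noHS with at most 3 (1 of 10), and the 729 between InRCA_noHS and control_HS with at most 0 (1 of 10). With 10 splits a share under 0.05 cannot be reached. For the 31 genes that set InRCA_HS apart from both other groups, 3 of 100 splits drawn from 840 gave as many, the real one included. That share is under 0.05, but the test was chosen after its result had been seen. It shows at most that the 9 libraries are not interchangeable, and does not bear on what sets InRCA_HS in particular apart. The highest other split gave 54 genes and kept the 3 control_HS libraries together against mixed InRCA libraries, and another gave 51 with the 3 InRCA_noHS libraries together, which points to a structure of the samples. The next highest of those drawn gave 2 genes, with the 3 InRCA_HS libraries together against mixed others. Without InRCA_HS replicate 1 the 31 genes became 4 higher and 0 lower (limma). Set against both other groups, control_HS had 138 genes (71 higher and 67 lower in both InRCA groups) and InRCA_noHS 163.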
